A study of Mus musculus with 6 samples.

How the data were processed

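Gene expression was measured on 6 Affymetrix arrays hybridised with labelled total RNA from mouse lung endothelial cells. Per the labels, the cells had been stably transfected either with an expression vector carrying full-length mouse L1CAM or with the empty vector, and were cultured for 4 days to confluence in medium with 20 percent serum. The labels give 3 replicates per group and describe them as biological replicates from independent experiments. They tell apart 1 transfectant per group, but do not say whether each was a pool or a clone, or whether more were used. The p-values measure the spread between replicate cultures, and whether this spread includes separate transfections is not known.

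The deposited values are log2 expression values per probe set, made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set on the log2 scale. Other settings of that step, and the genome build behind the array design, are not given in the sources used here, so no coordinates are printed and only chromosome names are used. Scanner files were not used here, and no detection calls were used, so dim probe sets near the background were not separated from expressed ones in the main test. The medians of the 6 arrays over all probe sets lay between 6.55 and 6.58, the lowest values between 2.02 and 2.20 and the highest between 13.7 and 13.8. The number of arrays, 3 per group, limits the precision.

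The table holds 35512 probe sets. Gene symbols came from the platform annotation, updated through Entrez identifiers to the GRCm38.p6 RefSeq gene table, which held 19856 of the identifiers and changed 0 symbols. A total of 21789 probe sets had 1 gene symbol, 1621 had several and 12102 were not listed. Only probe sets with 1 symbol were tested. For the 998 genes with more than 1 such probe set, the probe set with the highest mean over the 6 arrays was used, which left 19938 genes.

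Differences between L1CAM and control cells were fitted on the deposited log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term. The test was two-sided and moderated, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All log2 differences are L1CAM minus control, and folds are 2 to the power of that difference. Values are means ± SD over 3 arrays, and SE is the moderated standard error of the difference. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

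A set of 33 gene lists, with 908 entries of which 859 were measured, was written from textbook knowledge before the data were examined. The lists cover the L1 family, endothelial identity and junctions, mesenchymal and matrix genes, angiogenic and developmental pathways, cytokine and interferon responses, growth and stress programmes, and markers of other cell types. Each list was tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes on the array. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Members called over all genes tested were counted, and also those passing when adjusted over the list alone.

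The rule for named genes was fixed before the data were examined. It takes L1cam, the 12 largest rises and the 12 largest falls among genes past the threshold whose L1CAM arrays all lie beyond all control arrays, up to 4 called members of each list per direction, and 20 index genes. Where no member of a list passed, the 2 with the smallest p were given as values. Unnamed clones and predicted genes were to be left out of the largest changes, and 0 had to be. The rule also allows up to 4 genes of a regional pattern weighed in the closing section.

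The scripts were tested on simulated data for the comparison of L1CAM with control cells over 19938 genes. Each gene was drawn independently, so the simulation cannot show how the list test behaves where genes vary together. In the real data the estimated correlation was 0.53 for interferon, 0.97 for cell cycle and 0.62 for ER stress and amino acid genes. With 50 genes changed at each size, 74% of those changed by 0.5 on the log2 scale were recovered, 94% of those changed by 1, 100% of those changed by 2 and 100% of those changed by 4. Among the unchanged genes of that simulation, 7 were called. With no gene changed, 0 genes were called. The lists were tested on the simulation with 200 changed genes, where no list was shifted on purpose and 0 lists were called. Raising the interferon list by 0.5 in those same data gave 1 called list.

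The alternatives were quantile normalization again, array medians set to 0, a filter on dim probe sets, the mean of a gene's probe sets, all probe sets, a variance prior with an intensity trend, a robust prior, array weights, the replicate number as a block, an ordinary linear model, a threshold on size with treat, and leaving out each array. Counts of called list members without L1CAM replicate 1, and chromosome medians over all genes, were added after the data had been seen. The replicate number is not part of the main design, because no label says that it marks a shared day or culture.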

Results

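The study compared mouse lung endothelial cells stably transfected with full-length L1CAM with the same cells carrying the empty vector. L1CAM is a transmembrane cell adhesion molecule of the immunoglobulin superfamily, best known from neurons. Expression of 19938 genes was measured on 3 control arrays and 3 L1CAM arrays, all from confluent cultures. Control arrays correlated with each other at 0.9982 to 0.9986 across the genes tested, and L1CAM replicates 2 and 3 at 0.9986. L1CAM replicate 1 stood apart, at 0.9948 and 0.9951 with the other L1CAM arrays and 0.9935 to 0.9952 with the control arrays. These are correlations across genes within pairs of arrays, and genes are not independent replicates. On the first principal component, which held 74.6% of the variance, L1CAM replicate 1 lay at 6.34, between the control arrays (-23.8 to -17.0) and L1CAM replicates 2 and 3 (28.0 and 28.3). On the second, which held 12.1%, L1CAM replicate 1 lay alone at -19.6, against 0.18 to 6.85 for the other arrays. It was therefore not only intermediate between the groups.

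The transfected gene was the most strongly raised gene that passed the test. L1cam, on chromosome X, measured 6.86 ± 0.41 in control cells and 10.60 ± 0.12 in L1CAM cells (log2, SD, n = 3 per group). The difference was 3.75 (SE 0.19), or 13.4-fold, with a limma adjusted p of 0.000112. The control arrays read 6.50, 6.77 and 7.31 and the L1CAM arrays 10.49, 10.60 and 10.73, so the arrays fell on the sides their labels name. The probes cannot tell the transfected copy from the endogenous gene.

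Beyond L1cam, interferon response genes and a joint list of amino acid shortage and ER stress genes were higher in L1CAM cells. Genes of cell division were lower. All 3 of these list results passed with the preset correlation but not with an estimated one (adjusted p = 0.53 for each), and the cell cycle mean was -0.40 in L1CAM replicate 1 against -1.52 and -1.45 in replicates 2 and 3. The limma test called 2999 genes (15.0%), of which 1366 were higher and 1633 lower in L1CAM cells. Of these, 335 differed by at least 1 on the log2 scale, with 130 higher and 205 lower. The median absolute difference of the called genes was 0.42, and the median difference of all genes was 0.02. In all 2999 called genes the 3 L1CAM arrays lay beyond the 3 control arrays. Such separation was seen in 34.6% of all genes, against 10% by chance. The number of calls depended on single arrays: it was 1809 without control replicate 1, 1033 without control replicate 2, 1064 without control replicate 3, 4952 without L1CAM replicate 1, 1366 without L1CAM replicate 2 and 1238 without L1CAM replicate 3. An ordinary linear model called 581 genes, array weights 5191, all probe sets 1945, and a test against a difference of 0.5 called 152.

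**Figure D1:**
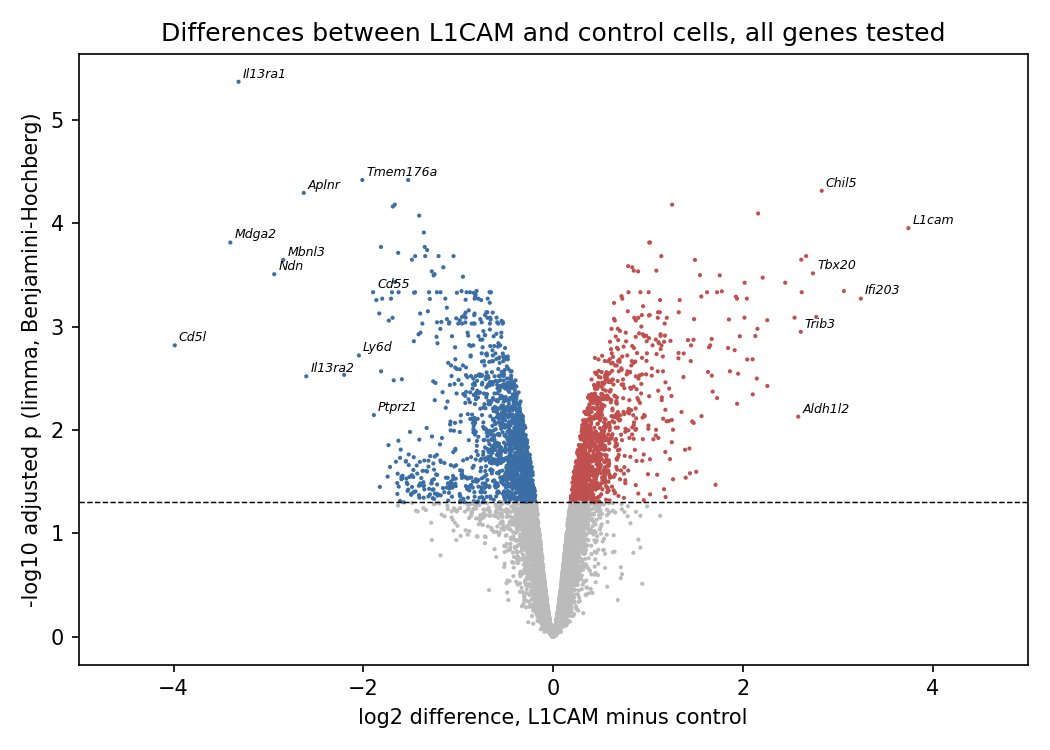
Log2 difference between L1CAM and control cells (x axis) against the negative log10 of the limma adjusted p (y axis) for all 19938 genes tested. Red points are the 1366 genes called higher, blue points the 1633 called lower, grey points genes not called, the dashed line the threshold of 0.05, and some of the genes with the largest changes are named.

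After L1cam, the largest rises came from interferon-inducible genes and from genes of several other kinds. Ifi203, of the interferon-inducible p200 family, rose by 3.24 (SE 0.26), or 9.47-fold, with an adjusted p of 0.000536. Oasl2, an interferon-induced relative of the oligoadenylate synthetases, rose 8.37-fold (adjusted p = 0.000453), and Ifit3b rose 6.84-fold. Ifit3b has a near-identical neighbour, Ifit3, so its probes may read both. Chil5, a chitinase-like protein, rose 7.12-fold (adjusted p = 4.85e-05), and Tbx20, a T-box transcription factor of heart development, 6.68-fold (adjusted p = 0.000305). Stmn2, a neuronal regulator of microtubules, rose 6.35-fold, from 5.48 ± 0.20 to 8.14 ± 0.30 (SD, n = 3 arrays). Tmem154 rose 6.15-fold, the ADAMTS-like matrix gene Adamtsl1 6.13-fold and Ebf1, a transcription factor of B cell development, 5.83-fold. Trib3, a pseudokinase induced by ER stress and amino acid shortage, rose 6.11-fold, and Aldh1l2, a mitochondrial enzyme of folate metabolism, by 2.58 (SE 0.41).

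The largest fall was that of Cd5l, a secreted protein best known from macrophages, from 10.83 ± 0.19 to 6.85 ± 0.98 (SD, n = 3 arrays). The difference was -3.99 (SE 0.42), 15.9-fold lower, with an adjusted p of 0.00152. Mdga2, a membrane-anchored protein of the immunoglobulin superfamily, was 10.6-fold lower. Both interleukin-13 receptor genes fell: Il13ra1 was 9.95-fold lower (adjusted p = 4.28e-06) and Il13ra2 6.07-fold lower. Il13ra1 read 5.19 ± 0.04 in L1CAM cells (SD, n = 3 arrays), near the lower quartile of all probe sets (5.01 to 5.04), and was not shown to be above background there, so its fold and its rank are not exact. Aplnr, the apelin receptor of endothelial cells, was 6.18-fold lower (adjusted p = 5.08e-05). Ndn, an imprinted growth suppressor, was 7.67-fold lower and Mbnl3, an RNA-binding splicing regulator, 7.18-fold. Ppp1r3c, a subunit that directs protein phosphatase 1 to glycogen, was 4.60-fold lower and Ly6d 4.13-fold. Tmem176a was 4.03-fold lower and has a close relative, Tmem176b, so its probes may read both, which was not tested. Cd55, an inhibitor of complement, was 3.72-fold lower, and Ptprz1, a receptor tyrosine phosphatase, 3.70-fold. Il13ra1, Il13ra2 and Mbnl3 lie on chromosome X, as L1cam does. Tmem176a and Ptprz1 lie on chromosome 6. Its median difference was -0.20 over the 497 genes above the array median on at least 3 arrays, and -0.04 over all 1099 genes. The lower group means of Ifi203, Chil5, Tbx20, Stmn2, Tmem154, Aldh1l2, Ndn, Mbnl3 and Cd55 also lay below the array medians (6.55 to 6.58), and their folds carry the same limit. All 24 genes of largest change, L1cam among them, were still called whichever array was left out.

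**Figure D2:**
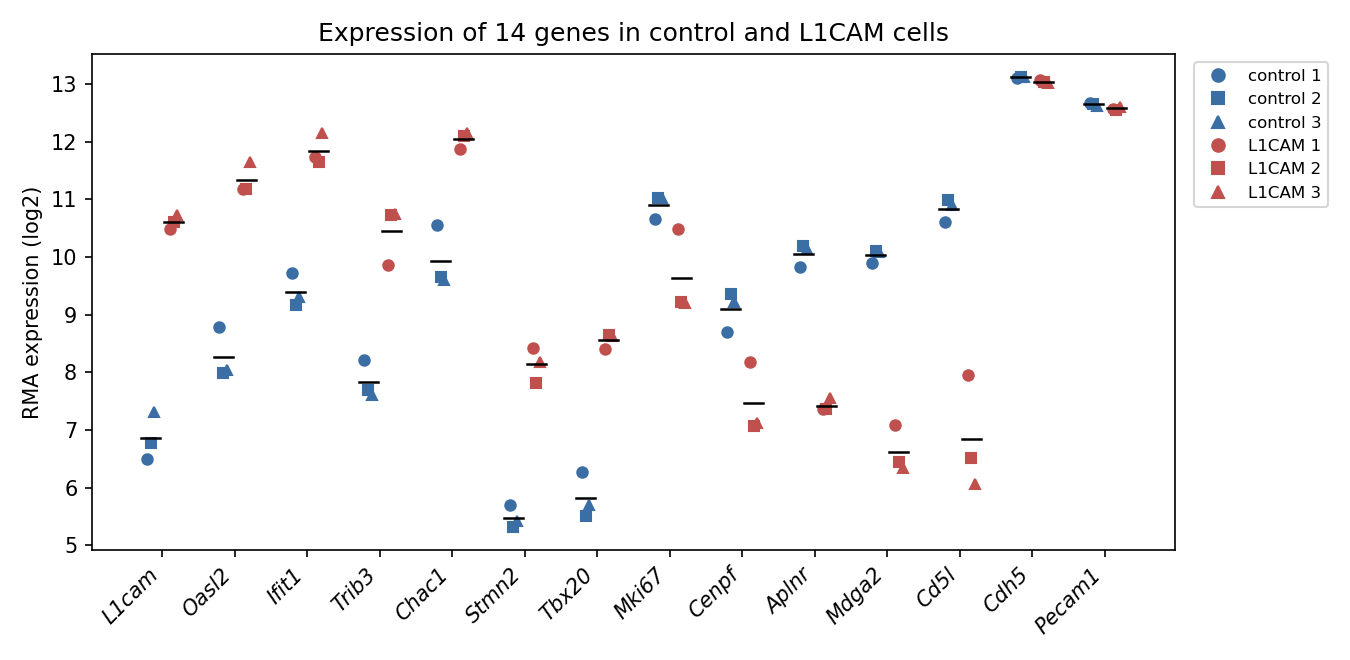
RMA expression (log2, y axis) of 14 named genes on each of the 6 arrays, with control arrays in blue, L1CAM arrays in red and group means as black bars. The 3 L1CAM arrays lie above the control arrays for L1cam, Oasl2 and Trib3 and below them for Cd5l, Mdga2 and Aplnr, and Pecam1 and Cdh5 differed by less than 0.1.

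Interferon response genes were higher as a group in L1CAM cells. Of 33 measured members, 21 rose and 0 fell, and 25 rose when adjusted over the list alone. The median difference of the list was 0.90, and camera gave an adjusted p of 1.67e-16 with the preset correlation. That call was lost with an estimated correlation (adjusted p = 0.53). Examples beside Oasl2 were Ifit1, which rose 5.45-fold (adjusted p = 0.000376), Usp18, a protease that removes ISG15, which rose 4.78-fold, and Ifih1, a sensor of viral RNA, which rose 4.62-fold. The list mean lay 0.98, 0.99 and 1.36 above the control mean in L1CAM replicates 1, 2 and 3, with control arrays at 0.17, -0.09 and -0.08. Leaving out any array gave 20 to 25 called members, with 25 without L1CAM replicate 1, an ordinary linear model called 6, and treat against 0.5 called 12.

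Cell cycle and mitosis genes were lower as a group. Of 41 measured members, 33 fell and 0 rose, and all 41 were lower when adjusted over the list alone. The median difference was -1.11, with a camera adjusted p of 6.91e-18, again lost with an estimated correlation (adjusted p = 0.53), and fry gave an adjusted p of 0.0756. Cenpf and Cenpe, kinetochore proteins, were 3.10-fold and 3.04-fold lower. Kif11, a spindle motor, was 3.03-fold lower and Bub1, a spindle checkpoint kinase, fell by 1.59. Mki67, the proliferation marker, was 2.41-fold lower (adjusted p = 0.0378). This list rested mostly on L1CAM replicates 2 and 3, where its mean lay at -1.52 and -1.45. It lay at -0.40 in L1CAM replicate 1, with control arrays at -0.19, 0.14 and 0.05. Single-gene calls were correspondingly unstable: over all genes tested, 41 members were called without L1CAM replicate 1, 6 without control replicate 1, and 0 without control replicate 2, control replicate 3, L1CAM replicate 2 or L1CAM replicate 3. Adjusted over the list alone, 37 to 41 members were called when any array was left out. An ordinary linear model and treat against 0.5 called 0 members each, also when adjusted over the list alone. A robust prior called 11 over all genes tested and 41 over the list alone.

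Genes of ER stress and the amino acid response, tested as a joint list, were higher as a group. The list was not split, so it does not show that both responses rose. Of 30 measured members 20 rose and 1 fell, or 21 and 2 adjusted over the list alone, with a median difference of 0.72. The camera adjusted p was 8.01e-10, and 0.53 with an estimated correlation. Trib3 and Aldh1l2 were followed by Chac1, a glutathione-degrading enzyme induced by ATF4, which rose 4.29-fold (adjusted p = 0.00207), and by the transcription factor Atf5, which rose 3.83-fold. The member that fell was Sdf2l1, an ER chaperone component (-0.48), which lost its call without control replicate 2 or 3. The list mean was 0.61, 0.93 and 0.97 in L1CAM replicates 1, 2 and 3, and 0.18, -0.10 and -0.08 in the control arrays. With any array left out, 15 to 22 members were called higher, 22 of them without L1CAM replicate 1. An ordinary linear model called 5 higher, and treat against 0.5 called 7.

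**Figure D3:**
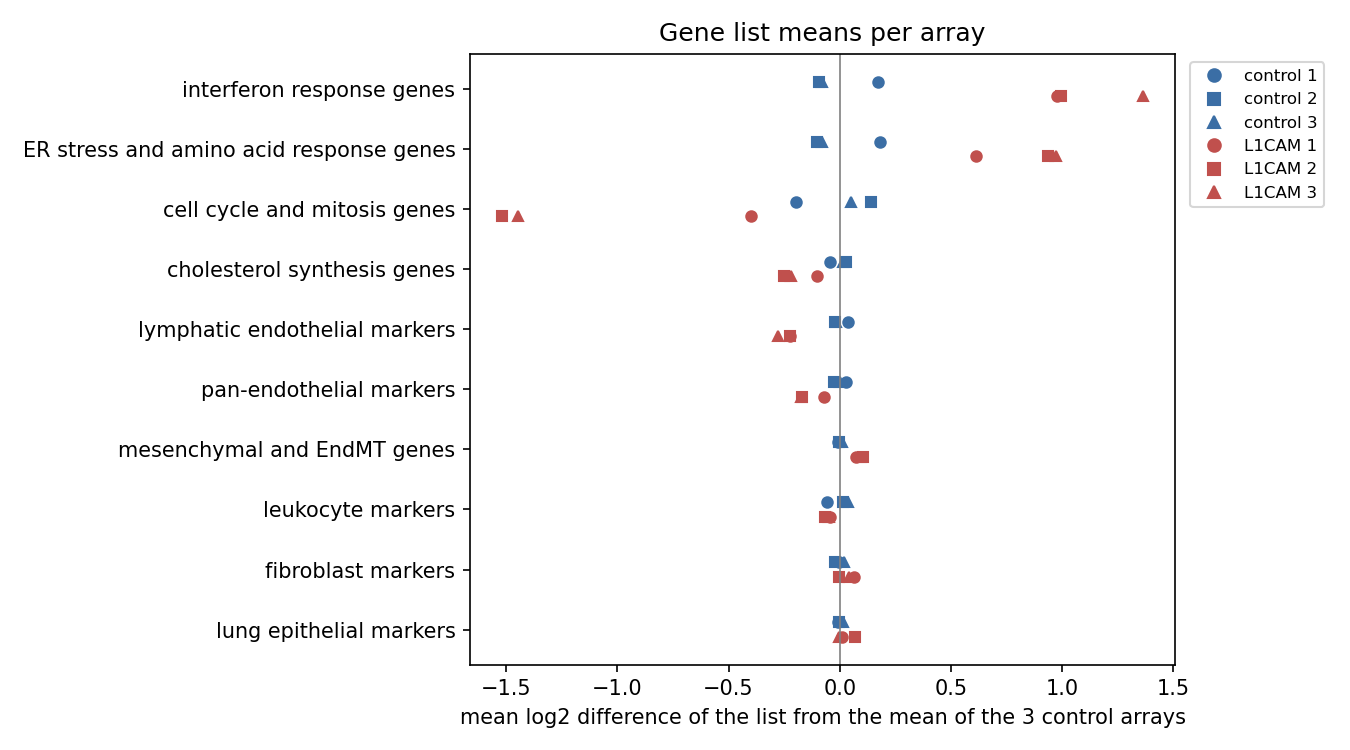
Mean log2 difference of the genes of 10 lists from the mean of the 3 control arrays (x axis), 1 point per array, with control arrays in blue and L1CAM arrays in red. L1CAM replicate 1 lies at 0.98 for interferon response genes, near replicate 2 at 0.99, but at -0.40 for cell cycle genes, where replicates 2 and 3 lie at -1.52 and -1.45.

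Cholesterol synthesis genes were lower as a group by a smaller amount, with a median of -0.22 and a camera adjusted p of 0.00131 (adjusted p = 0.53 with an estimated correlation). Of 18 members 5 fell, or 8 adjusted over the list alone, among them Stard4, a sterol carrier (-0.74), and the synthesis enzymes Idi1 (-0.37), Sc5d (-0.30) and Cyp51 (-0.30). The probe set of Idi1 is numbered among those of genes on another chromosome, so it may read another locus, which was not tested. The list mean was -0.10 in L1CAM replicate 1, against -0.25 and -0.22 in replicates 2 and 3. An ordinary linear model called 0 members. The number of called members was 5 without control replicate 1, 0 without control replicate 2 or 3, 10 without L1CAM replicate 1, 1 without L1CAM replicate 2 and 0 without L1CAM replicate 3.

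Pan-endothelial markers had members that moved both ways. Of 29 members 4 rose and 6 fell, or 4 and 9 adjusted over the list alone, with a median of -0.08 and a camera adjusted p of 0.0122. The list did not pass with an estimated correlation (adjusted p = 0.53) or with the filter on dim probe sets (adjusted p = 0.137), and its mean was -0.07 in L1CAM replicate 1 against -0.17 in both replicates 2 and 3. Clec14a, an endothelial surface lectin, was 2.84-fold lower, and Flt1, a VEGF receptor (-0.82), Mmrn2 (-0.65) and the transcription factor Fli1 (-0.52) also fell. Sox17, a transcription factor of arterial endothelium, rose 2.12-fold, and Robo4 (0.44), Nos3 (0.25) and Tal1 (0.19) rose. Clec14a and Robo4 lost their calls without control replicate 2, and the other members named here without control replicates 2 and 3 at least. The core markers Cdh5 (-0.08, adjusted p = 0.37), Pecam1 (-0.07, adjusted p = 0.41), Kdr (0.01, adjusted p = 0.95), Tek (-0.08, adjusted p = 0.37) and Vwf (-0.01, adjusted p = 0.93) did not pass the test. Among the members 5 were called without control replicate 1, 0 without control replicate 2, 2 without control replicate 3, 14 without L1CAM replicate 1, 5 without L1CAM replicate 2 and 4 without L1CAM replicate 3. Lymphatic endothelial markers had 2 of 14 members lower and 0 higher, or 4 lower adjusted over the list alone, with a median of -0.10. These were Nrp2, a co-receptor for VEGF-C and semaphorins (2.31-fold lower), and Stab1, a scavenger receptor (2.23-fold lower), both called whichever array was left out. The camera adjusted p was 0.0333, became 0.0913 without control replicate 1 and 0.0541 with the filter on dim probe sets, and was 0.53 with an estimated correlation. Without L1CAM replicate 1, 5 members were lower. In the list of arterial and venous genes 5 of 24 rose and 4 fell, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.63). Sox17, Dll4 and Vcam1 were among the rises and Aplnr, Nrp2 and Nrp1 among the falls. Its median (0.01) differed in sign from its mean (-0.07) and its test.

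The remaining 27 lists did not pass the camera test, and their members are given as counts with examples. Together 173 of their 694 list entries were called, a number that was 125 without control replicate 1, 81 without control replicate 2, 80 without control replicate 3, 258 without L1CAM replicate 1, 99 without L1CAM replicate 2 and 93 without L1CAM replicate 3. Of 181 called genes that are named here or among the additional observations, L1cam not counted, 98 remained called in all 6 of these fits.

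Junction, adhesion and matrix genes changed one by one. Of 25 junction and polarity genes 3 rose and 5 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.39). Gja1, the gap junction protein connexin-43, rose 2.33-fold and Pard3, a polarity protein, by 0.74, while Afdn rose by 0.32. Jam2, a junctional adhesion molecule, was 1.94-fold lower, and Nectin2 (-0.60), Ocln (-0.48) and Vcl (-0.28) fell. Of 27 mesenchymal and endothelial-to-mesenchymal transition genes 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.41). Cd44, a hyaluronan receptor, rose 2.16-fold, Cdh2, N-cadherin, by 0.66, Zeb1 by 0.26 and Cnn1 by 0.23, and Fn1, fibronectin, fell by 0.49. Vim (-0.02, adjusted p = 0.83), Acta2 (-0.08, adjusted p = 0.71) and Snai1 (-0.12, adjusted p = 0.18) were not called. Snai2 (-0.23, adjusted p = 0.37) was not called either, but gave -0.42 without L1CAM replicate 1 (adjusted p = 0.00703). Of 36 collagen and extracellular matrix genes 1 rose (Lox, 0.24) and 5 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.34). Fbln2 was 2.74-fold lower, with Lamb1 at -0.70 and Lama4 at -0.27, and the list's median (0.01) differed in sign from its mean (-0.07) and its test. Of 25 matrix proteases and inhibitors 3 rose, Adamts9 (1.13), Mmp11 (0.34) and Timp3 (0.24), and 2 fell, Mmp14 (-0.52) and Plau (-0.22), or 3 and 3 adjusted over the list alone (camera adjusted p = 0.67). Of 19 integrins 4 rose and 2 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.35). Itga4 (0.55), Itgb5 (0.39), Itga3 (0.35) and Itga7 (0.30) rose, and Itgb8 (-1.02) and Itgav (-0.66), a known partner of L1CAM, fell. Itgb1 measured -0.20 (adjusted p = 0.052), and -0.23 without L1CAM replicate 1 (adjusted p = 0.0218). Ocln, Cnn1, Lox, Itga4, Itgb5, Itga7, Itgb8 and Acta2 had at least 1 group mean below the array medians, so these genes were not shown to be above background there and their differences are not exact. Gja1, Pard3, Jam2, Nectin2, Ocln, Cd44, Fbln2, Lamb1, Adamts9, Mmp14, Itgb8 and Itgav kept their calls whichever array was left out, and the other called genes of this paragraph did not.

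Genes of vessel growth were mixed. Of 33 angiogenic growth factors and receptors 4 rose and 8 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.17). The growth factors Vegfc (2.27-fold), Vegfa (1.84-fold), Pgf (1.75-fold) and Hbegf (1.69-fold) rose. Aplnr, Pdgfc (2.64-fold lower), Nrp2 and Flt1 fell, and Fgfr1 measured -0.11 (adjusted p = 0.31). Of 17 tip cell and sprouting genes 4 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.30). Igfbp3 rose 2.02-fold, and the Notch ligand Dll4 (0.63) and Ramp3 (0.40) also rose, while the netrin receptor Unc5b fell by 0.46. Of 20 Notch pathway genes 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.13): Jag2 (0.64), Dll4, Efnb2 (0.34) and Jag1 (0.27). Of 34 TGF-beta and BMP pathway genes 6 rose and 4 fell, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.51). Ccn2 (0.87), Bmpr1a (0.83), Inhbb (0.55) and Bmp2 (0.53) rose, and Tgfb3 was 2.34-fold lower, with Ltbp1 at -0.59, Tgfbr3 at -0.52 and Bmpr2 at -0.31. Of 30 Wnt pathway genes and targets 2 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.17). Wnt5a (-1.03), Fzd7 (-0.70), Lrp5 (-0.50) and Tcf7l2 (-0.45) fell, and Fzd4 (0.43) and Notum (0.21) rose. Bmpr1a and Bmp2 read 4.66 and 4.67 in control cells, below the lower quartile of all probe sets, and Wnt5a and Notum also had at least 1 group mean below the array medians, so the differences of these 4 genes are not exact. Hbegf, Flt1, Ramp3, Unc5b, Efnb2, Jag1, Inhbb, Bmpr2, Tcf7l2, Fzd4 and Notum lost their calls with at least 1 array left out, and the other called genes of this paragraph kept theirs.

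Signalling by cytokines was examined because several of the index genes belong to it. Of 28 genes of the IL-6 family, JAK and STAT3, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.13). Socs2 (0.82), Cebpb (0.67), the receptor Il6ra (0.60) and the survival gene Bcl2l1 (0.55) rose, and Pias1 (-0.29) and Pim1 (-0.27) fell. The probe set of Socs2 is numbered among those of genes on another chromosome, so it may read another locus, which was not tested. Il6 itself was not called, with a difference of 0.68 (SE 0.51, adjusted p = 0.44). Its L1CAM arrays read 4.75, 6.55 and 6.95 against 5.79, 5.19 and 5.23 in controls, and without L1CAM replicate 1 the difference was 1.35 (adjusted p = 0.00135). With array weights it was 1.23 (adjusted p = 0.0287). Stat3 (0.07, adjusted p = 0.46) was not called, and Il6st, the shared receptor subunit (0.21, adjusted p = 0.064), passed without L1CAM replicate 1 (adjusted p = 0.0368). Of 34 cytokines and chemokines 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.34). Cxcl10, an interferon-induced chemokine, rose 3.84-fold, Ccl5 2.35-fold, Csf1 by 0.58 and Tslp by 0.50, and Il33 fell by 0.76. Of 22 NF-kappaB targets and leukocyte adhesion genes 6 rose and 2 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.39). Ptgs2, cyclooxygenase-2, rose 2.38-fold, Tnfaip2 by 0.51, Tnfaip3 by 0.49 and Vcam1 by 0.41, and the inhibitors Nfkbie (-0.55) and Nfkbia (-0.49) fell. Il6, Tslp, Il33 and Vcam1 had both group means below the array medians, so they were not shown to be above background and their differences are not exact. Cebpb, Bcl2l1, Pias1, Pim1, Ccl5, Csf1, Tslp, Ptgs2 and Tnfaip3 lost their calls with at least 1 array left out, and the other called genes of this paragraph kept theirs.

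Further growth and stress programmes also moved both ways. Of 25 cyclins, CDK inhibitors and p53 targets 5 rose and 9 fell, or 6 and 11 adjusted over the list alone (camera adjusted p = 0.064). Gadd45a rose 2.71-fold, and Cdk6 (0.69), Gadd45b (0.64) and Gadd45g (0.59) rose. Btg2 (-0.96), Trp53inp1 (-0.88), Sesn1 (-0.49), Pmaip1 (-0.42) and cyclin D1, Ccnd1 (-0.31), fell. Of 33 hypoxia and glycolysis genes 4 rose and 5 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.61). Vegfa, Ndrg1 (0.79), Pfkp (0.64) and Pgk1 (0.26) rose, and Pdk3 (-1.31), Tpi1 (-0.51), Car9 (-0.47) and Bnip3 (-0.30) fell. The probe sets of Pgk1 and Bnip3 are numbered among those of genes on other chromosomes, so they may read other loci, which was not tested. Of 28 MAPK feedback and immediate early genes 6 rose and 2 fell, or 7 and 2 adjusted over the list alone. Its camera adjusted p was 0.059, 0.0282 without control replicate 3 and 6.59e-05 without L1CAM replicate 1, where 15 rose. With an estimated correlation the adjusted p was 0.70 over all arrays and 0.525 without L1CAM replicate 1. Ier3 (0.83), Hbegf, Phlda1 (0.68) and Ereg (0.62) rose, and Etv1 (-0.96) and Etv5 (-0.46) fell. Of 24 YAP and SRF target genes 6 rose and 4 fell, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.48). The receptor kinase Axl rose 2.27-fold, with Ccn2, Ccn1 (0.67) and Amotl2 (0.32), and Cnn2 (-0.56), Tead1 (-0.29), Vcl and Amotl1 (-0.25) fell. Cdk6, Btg2, Trp53inp1, Vegfa, Ndrg1, Pfkp, Pdk3, Tpi1, Etv1, Axl, Ccn2 and Ccn1 kept their calls whichever array was left out, and the other called genes of this paragraph did not.

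Genes that share a setting with L1CAM in neurons changed in part. Of 21 genes of the L1 family and its binding partners 2 rose, L1cam and Ank2 (0.59), and 3 fell, Itgav, Ezr (-0.44) and Nrp1 (-0.38), or 2 and 5 adjusted over the list alone (camera adjusted p = 0.51). The median of this list (-0.01) and its test pointed down and its mean (0.10) up. Of 47 axon guidance genes 10 rose and 7 fell, or 15 and 10 adjusted over the list alone (camera adjusted p = 0.52). The semaphorins Sema3d (1.42) and Sema3c (1.19), Ntn4 (0.61) and Plxna4 (0.45) rose, and Nrp2, Sema6a (-0.61), Unc5b and Epha4 (-0.44) fell. Of 24 neuronal and Schwann cell genes 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.096): Stmn2, the RNA-binding protein Elavl4 (0.60) and the neurofilament Nefm (0.50). Sema3d and Sema3c read 5.19 and 5.16 in control cells, near the lower quartile of all probe sets, and Ank2, Stmn2, Elavl4 and Nefm also had at least 1 group mean below the array medians, so the differences of these 6 genes are not exact. Ank2, Ezr, Sema3c, Sema6a, Unc5b and Epha4 lost their calls with at least 1 array left out, and the other called genes of this paragraph kept theirs.

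Markers of other cell types moved little. No member of the lists of 23 leukocyte and 22 lung epithelial markers was called by limma (0 of each, also when adjusted over the list alone), with camera adjusted p values of 0.46 and 0.61. At an unadjusted p under 0.05 the lists had 2 members each, and an ordinary linear model called 0. The smallest p values belonged to Itgax (-0.36, adjusted p = 0.079) and Cd79a (-0.29, adjusted p = 0.097) among leukocyte markers and to Esrp1 (0.16, adjusted p = 0.15) and Krt19 (0.17, adjusted p = 0.15) among epithelial ones. Itgax passed without control replicate 1 (adjusted p = 0.0160) and Cd79a without control replicate 2 (adjusted p = 0.0256), both lower in L1CAM cells. Of 19 fibroblast markers 0 rose and 1 fell (Gsn, -0.46), also when adjusted over the list alone (camera adjusted p = 0.86). Of 18 pericyte and smooth muscle markers 1 rose (Cnn1) and 2 fell (Smtn, -0.58, and Anpep, -0.53), also when adjusted over the list alone (camera adjusted p = 0.83). No ribosomal protein gene was called among 18 (0 also when adjusted over the list alone, camera adjusted p = 0.27), the smallest p values being those of Rpl8 (-0.10, adjusted p = 0.33) and Rps18 (-0.08, adjusted p = 0.42). At an unadjusted p under 0.05 there were also 0, and 0 with an ordinary linear model. Of 18 imprinted and germline genes 1 rose (Grb10, 0.31) and 2 fell (Mest, -0.64, and Xist, -0.29), or 2 and 2 adjusted over the list alone (camera adjusted p = 0.61). Median, mean and test differed in sign for the leukocyte (0.006, -0.05 and down), fibroblast (0.03, 0.04 and down), pericyte (0.02, -0.05 and down) and imprinted lists (0.007, -0.05 and down). Itgax, Cd79a, Esrp1, Krt19, Cnn1 and Anpep had both group means below the array medians, so they were not shown to be above background. The filter on dim probe sets kept only 2 leukocyte, 3 lung epithelial, 5 fibroblast and 2 pericyte and smooth muscle markers. Most members of these lists were therefore dim. Smtn, Anpep and Mest kept their calls whichever array was left out, and Gsn, Cnn1, Grb10 and Xist did not.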

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

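The tests of a mixed sample, of a wrong label and of a compressed array were chosen only after the position of L1CAM replicate 1 had been seen, the last in place of a planned test of its interquartile range, which was void because normalization between arrays makes these ranges nearly equal. Among the 13723 probe sets with no single gene symbol, which the comparison did not use, limma on all probe sets called 385, of which 186 were higher and 199 lower in L1CAM cells and 97 differed by at least 1 on the log2 scale. They were set aside because their signal lies outside the genes tested, and no gene name is given to them.

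L1CAM replicate 1 lay nearer to the control arrays than L1CAM replicates 2 and 3: over the 335 genes that differed by at least 1, its difference from the control mean was 0.63 of theirs (quartiles 0.33 and 0.83). A wrong label is argued against by its L1cam level, which lay 3.18 above the highest control array, with an SD of 0.41 over the control arrays. A dim or compressed array would shrink genes of like level alike, but the median ratio to replicates 2 and 3 was 0.872 (quartiles 0.82 and 0.93) for the 12 called interferon genes within the control level range of the 33 called cell cycle genes, and 0.285 (quartiles 0.25 and 0.34) for these. The interferon genes rose and the cell cycle genes fell, and they were matched only on control level. A compression that acts on low or on high values alone is therefore not excluded. Control RNA mixed into it would give 1 share of L1CAM-cell RNA for all changed genes, but the called interferon genes needed a median share of 0.780 (quartiles 0.66 and 0.82) and the called cell cycle genes 0.39 (quartiles 0.36 and 0.46). A biological difference between replicate cultures, such as their growth state at harvest, may remain and was not tested.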

How the results depend on the processing

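Among the 19938 genes tested, no gene called both in the main test and under another setting changed direction. L1cam stayed past the threshold in each of these settings, with limma or linear model adjusted p between 1.8e-05 and 0.0332. Neither point was checked over all probe sets. Called genes (in all, higher, lower) numbered 5191, 2557 and 2634 with array weights, 581, 251 and 330 with an ordinary linear model, 152, 80 and 72 with treat against 0.5, and 1945, 884 and 1061 over all probe sets. Genes differing by at least 1 numbered 104 with the ordinary model and 139 with treat. Leaving out each array in turn gave 1033 to 4952 genes in all, 454 to 2386 higher, 579 to 2566 lower and 188 to 508 that differed by at least 1, with an L1cam difference of 3.56 to 3.97. Quantile normalization again gave 3111 genes, array medians set to 0 3115, the filter on dim probe sets (10092 genes kept) 3347, the mean of probe sets 3006, the trend 3256 and the robust prior 2871. Of 33 lists, 0 passed with an estimated correlation and 15 with fry. The main test passed 6, and 5 to 7 with an array left out. The causes were not tested. Fry passed the interferon (adjusted p = 0.0169), ER stress (0.0241), cholesterol (0.0292), pan-endothelial (0.0231) and lymphatic (0.00673) lists, but not the cell cycle list (0.0756). It also passed the junction, mesenchymal, protease, integrin, angiogenic, tip cell, Notch, Wnt, cyclin and neuronal lists. These did not pass camera in the main test. With the dim filter the pan-endothelial (adjusted p = 0.137) and lymphatic (adjusted p = 0.0541) calls were lost. MAPK genes passed with quantile normalization, the trend, array weights and the block, and cyclins and p53 targets with medians set to 0 and the trend. Among 181 called named genes beside L1cam, 127 lost the call with the ordinary model, 135 with treat, 80 without control replicate 2 and 0 without L1CAM replicate 1. Il6st and Itgb1, not called in the main test, passed with the dim filter, the trend and array weights, and Snai2 and Itgax with array weights. Camera offers no robust prior, so that setting was not run for lists, and pseudocounts were not run because the values are log2. The 10 splits of 6 arrays are too few for a share under 0.05: the real split gave 2999 genes and the highest other 0 (as many in 1 split, the real one), and 6 lists against 7 for the highest other, which groups L1CAM replicate 1 with control replicates 1 and 2 (as many in 2 splits). Signal over background was not available to grade dim genes.

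With the replicate block, 2067 genes were called (923 higher, 1144 lower, 255 differing by at least 1), 1970 of them also in the main test; 31 named genes lost the call, and 9 cell cycle genes were called. Same-numbered arrays correlated at -0.10, -0.10 and -0.03 in their deviations from the group means. Of 3 control arrays, 0 correlated best with their own number. Deviations from a mean of 3 arrays sum to 0, so these values gave no sign of pairing but cannot exclude it.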

Other observations

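The tests of the 6 further gene lists, of leukocyte RNA, growth state and separate transfectants for the interferon genes, and of chance for chromosome 6 were chosen only after the results had been seen, as were the genes named from those lists. Genes that charge transfer RNAs with amino acids rose with the amino acid response. Of 18 aminoacyl-tRNA synthetase genes 15 rose and 1 fell, with a median of 0.75, among them Cars (2.36-fold, limma adjusted p = 0.00137), Tars (1.18), Mars1 (1.11) and Lars (1.09), while Qars fell by 0.42. Camera gave an adjusted p of 7.66e-12, and 0.239 with an estimated correlation. Of 16 amino acid transporters 9 rose and 1 fell (median 0.66, camera adjusted p = 0.000255, and 0.239 with an estimated correlation), led by Slc1a4 (4.45-fold) and Slc6a9 (4.30-fold), followed by Slc7a5 (1.91) and Slc1a5 (1.56). Slc7a5 and 3 other transporters also belong to the ER stress and amino acid list. Among 12 MHC class I presentation genes 4 rose, Erap1 by 0.94 and Psmb10 by 0.55 among them, and the list did not pass (camera adjusted p = 0.108).

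Lower genes of cell division reached beyond the fixed list. Of 30 condensin, cohesin and kinetochore genes 18 fell and 0 rose (median -1.14, camera adjusted p = 1.67e-10), among them Esco2 (-1.83) and Cdca5 (-1.66), regulators of sister chromatid cohesion. Of 26 homologous recombination and Fanconi genes 14 fell and 0 rose (median -0.72, camera adjusted p = 6.43e-08), among them Exo1 (-1.47) and Brca1 (-1.43). Both had an adjusted p of 0.239 with an estimated correlation, and both rested mostly on L1CAM replicates 2 and 3: the first list had means of -1.32 and -1.25 there and -0.35 in L1CAM replicate 1. Without L1CAM replicate 1, 23 and 20 members fell. Esco2, Cdca5, Exo1 and Brca1 lost their calls without control replicate 2 or 3 or L1CAM replicate 2 or 3, and Esco2, Exo1 and Brca1 also without control replicate 1, with adjusted p of 0.0557 to 0.135. Of 10 HoxA cluster genes 4 fell and 0 rose (median -0.22, camera adjusted p = 0.000297, and 0.239 with an estimated correlation), with Hoxa2 at -0.92 and Hoxa5 at -0.53. They lie on chromosome 6.

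The rise of interferon response genes was set against 3 explanations. RNA of leukocytes in the L1CAM cultures is argued against by the leukocyte markers, of which 0 were called and whose median difference was 0.00604. The filter on dim probe sets kept only 2 of these markers, so a small amount of leukocyte RNA could have gone unseen. The growth state that goes with the lower cell cycle genes stays open. L1CAM replicate 1 had 0.830 of the mean interferon rise of replicates 2 and 3 and 0.268 of their cell cycle fall, but this rests on 1 array and the interferon means of replicates 2 and 3 themselves differed (0.99 and 1.36). A difference between the transfected cell populations other than L1cam itself, such as a clonal difference, may be the source and cannot be told apart from L1CAM, since the labels name only 1 L1CAM transfectant.

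Genes of chromosome 6 were lower together in L1CAM cells, which was found in the data and tested on them. Over its 497 genes above the array median on at least 3 arrays the median was -0.20, 80.5% were lower, and 42.9% were called lower against 12.8% on the other chromosomes; Tmem176a, Ptprz1, Mansc1 (-1.67) and Tmem176b (-1.53) fell furthest, Mansc1 to below the array medians, so that its difference is not exact. Chance variation of neighbouring genes is argued against by circular shifts along the genome (adjusted p = 0.044 over 20 chromosomes, the only one past 0.05). However, over all 1099 genes, an alternative added later, the median was -0.04 and the adjusted p 0.066, so this depended on the filter. Of these 1099 genes 58.7% were lower and 229 were called lower. The growth state stays open: the chromosome 6 median of L1CAM replicate 1 was 1.09 times that of replicates 2 and 3, above the bound of 0.6 set beforehand, but that bound rested on 1 array and so excludes nothing. Fewer copies of chromosome 6 in the L1CAM cells are a candidate explanation. It was weighed only by evenness over arrays and along the chromosome. The size of the shift was not set against that of a lost copy. The 3 L1CAM arrays lay at -0.22, -0.20 and -0.21 against -0.003 to 0.003 in the controls. The medians of 4 consecutive parts of the chromosome with nearly equal numbers of genes were -0.142, -0.199, -0.228 and -0.245 in gene order. All were below 0, but the fall grew along the chromosome. Such evenness over the L1CAM arrays was also seen on some, but not all, chromosomes that did not pass. Chromosome 13 lay at 0.12, 0.13 and 0.14 and chromosome 12 at -0.10, -0.09 and -0.09 (circular shifts, adjusted p = 0.28 each). Chromosome 8 was uneven, at 0.12 in L1CAM replicate 1 against 0.02 and 0.01 in replicates 2 and 3 (circular shifts, adjusted p = 0.36). The cause of that difference between the L1CAM arrays was not tested. Expression alone does not count chromosomes.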
